A study of Nicotiana tabacum with 4 samples.

How the data were processed

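Leaves of tobacco, Nicotiana tabacum cultivar NC89, were profiled after 4 treatments, with 1 sequencing library per treatment. Per the labels, 6 plants were used in each treatment and comparable leaves were harvested from them. With a single library per treatment, the files carry no measure of the spread between plants. The groups were mock inoculation, infection with TYLCCNV (tomato yellow leaf curl China virus, a begomovirus) and its satellite DNA, whitefly infestation of mock-inoculated plants, and infestation of infected plants, called the joint treatment here. Per the labels' protocols, the virus was introduced by agroinoculation, in which Agrobacterium carries the viral clone into the plant, and mock plants received the same Agrobacterium strain. About 6000 adult whiteflies were released per cage at 22 days after inoculation and fed for 72 h. The labels date the mock and virus samples to 25 days after inoculation.

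Each deposited file lists sequence tags with a copy number and a TPM value, per the file headers. All tags in the files were 21 bases long and began with CATG, which is the site of the enzyme NlaIII, although the enzyme is not given in the sources used here. Per the labels' protocols, total RNA was extracted and the libraries were built to the sequencing vendor's instructions. The copy numbers deposited by the authors were whole-number counts of at least 2, so that tags seen once were absent from the files. The TPM values deposited by the authors equalled copies per 1000000 copies of the file to within 0.005, and they add nothing to the counts. The read filters, aligner and genome build are not given in the sources used here.

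The total was 3514340 copies over 120558 distinct tags in the mock library, 3571141 over 120219 in the virus library, 3370253 over 126741 in the whitefly library and 3418410 over 145243 in the joint library. At these totals 1 copy corresponds to 0.280 to 0.297 TPM. The intervals of folds and ratios are exact 95% intervals and cover counting error only. Those of shares of tags are exact binomial 95% intervals that treat tags as independent, which they are not. The counts carry no molecular identifiers, so amplified copies of 1 molecule cannot be separated from independent molecules.

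No tag was assigned to a gene. The annotation table used here holds names and coordinates of 79372 genes but no sequence, and tags were therefore reported by sequence. The 31 gene lists fixed before the data were examined, the comparison of sites nearest the transcript end with all sites, and the treatment of tags matching several genes could not be applied.

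Fold changes were computed from counts scaled to library totals with a prior of 0.5 copies. A tag was listed as higher or lower when its fold was at least 2, the larger of both libraries held at least 20 copies, and the exact 95% conditional binomial interval of the ratio excluded 1. A tag missing from a file entered that interval as 1 copy. With 1 library per treatment, no p-value or SE was attached to any comparison between treatments, and a listed difference is one between libraries. Departure from additivity was the log2 value of the joint library minus those of the virus and whitefly libraries plus that of the mock library, listed at 2-fold or more where its 95% normal interval excluded 0. The rule for naming tags took, per comparison, the 2 tags with the largest rise and the 2 with the largest fall among those with at least 50 copies in the higher library, and the 4 most abundant tags of each library. These rules were fixed before the data were examined. Further tags, said to be so where they appear, were chosen after their values were seen. They had at least 50 copies in all 4 libraries, no run of 8 A, no index bases in them or at their end, and were listed with and without the centring described next; the smaller of both folds ranked them. Of the tags chosen in this way, 1 is not reported here.

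Examination of the counts showed that folds depended on the last 2 bases of the tag and that some tags contained a library-specific sequence. The commonest 10-base sequence followed by TCG among tags private to a library, called its index sequence here, was ACTACACATC in mock, TGACCATTGT in virus, TGGACTACTG in whitefly and TTAGATCAGG in the joint library. The labels do not describe it. After seeing the data, 3 settings were added: folds centred on the median of tags with the same last 2 bases, estimated from 23543 tags with a mean of at least 20 copies, the omission of tags holding 6 bases of any index sequence, and both together.

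Other settings, chosen at the same time as the rules, were edgeR TMM factors, DESeq2 size factors, no minimum count, a minimum of 100 copies, a fold threshold of 4, an interval lying wholly beyond 2-fold, and a prior of 5 copies. An additive model of virus and whitefly over all 4 libraries was fitted to the counts with edgeR's quasi-likelihood test, in which the interaction supplies the only residual degree of freedom. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and Biopython 1.88, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, were used. The listing rule was tested on simulated counts. For the joint against mock comparison, simulated over 184175 tags, it recovered 98 of 100 tags changed 2.83-fold and 100 of 100 changed 8-fold, and it listed 402 unchanged tags through counting noise. The additive edgeR fit, simulated over 12809 tags with a biological coefficient of variation of 0.316, recovered 6 of 100 tags changed 2-fold and 100 of 100 changed 8-fold, and called 1 unchanged tag. At 0.49, the common value fitted to the real counts, it recovered 0 of 100 changed 2-fold and 41 of 100 changed 8-fold, and called 2 unchanged tags.

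Sequences of tags nearly absent from the libraries made without whiteflies, or from those made without the virus, are not printed. These tags are not known to come from tobacco. Exceptions are tags that encode a stretch of a pathogenesis-related or photosynthesis protein, or that hold an index sequence.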

Results

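Expression in tobacco leaves was measured as counts of 21-base sequence tags after mock inoculation, TYLCCNV infection, whitefly infestation and the joint treatment, with 1 library of 3370253 to 3571141 copies for each. In all, 239095 distinct tags were counted, of which 59378 were seen in all 4 libraries and 35700 reached 20 copies in at least 1. The 10 most abundant tags made up 7.41% to 8.25% of a library. The comparisons address how the plant responds to a begomovirus, to the insect, and to both together. No comparison has replicates, so each difference below is one between libraries, with an interval for counting error only.

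CATGTTCGGGTGCACTGATGC and CATGTTTGGGTGCACTGATGC, which differ at 1 position, were among the 4 most abundant tags of every library. CATGTTCGGGTGCACTGATGC stood at 12857 TPM in mock, 18921 in virus, 14329 in whitefly and 18752 in the joint library. CATGTTTGGGTGCACTGATGC stood at 12894, 14251, 9516 and 14519 TPM in the same order, and no comparison of either tag reached 2-fold. CATGTGGAAGCTACCTATGTT, the most abundant tag of the mock and whitefly libraries, stood at 16362 TPM in mock, 16769 in virus and 17765 in whitefly but at 3039 in the joint library. That is 5.39-fold lower than in mock, and a log2 fold of −2.43 became −0.64 once folds were centred on tags with the same last 2 bases. CATGCAGCAAAGACCAAGAAC fell from 10175 TPM in mock to 4868 in the joint library, a log2 fold of −1.06, or −1.28 after the same centring. The joint library counted among its 4 most abundant tags CATGTAATGTTTTGTTGTACA, at 9442 TPM against 5040 in mock, and CATGGACTCAAGGAGGTCAAG, at 8068 against 5776.

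The comparison of infected with mock plants sets the virus library against mock, without whiteflies in either. In the virus library 5037 tags were listed higher and 4469 lower, of 28265 with at least 20 copies in either library. The balance turned with other scalings, to 4336 higher and 4919 lower with edgeR TMM factors and 4516 and 4800 with DESeq2 size factors. Centred by the last 2 bases, 3761 were higher and 3419 lower, and 2856 and 2720 of these were also listed without centring. The 2 largest rises were CATGCAAGAGTGCTAATTTGA, with 1177 copies in virus and none listed elsewhere, and CATGTTGAGCTTTAAGGATTG, with 1025 copies in virus, 450 in whitefly and none listed in mock or joint. The 2 largest falls were CATGCAAGAGTGCTAATTACT, with 1208 copies, and CATGGGACACTACACATCTCG, with 1038, both listed in mock alone. CATGGGACACTACACATCTCG holds all 10 bases of the mock index sequence. CATGCAAGAGTGCTAATTTGA and CATGCAAGAGTGCTAATTACT share their first 18 bases and end in the first 3 bases of the virus and of the mock index. The second of the 2 largest rises ends in the 2 bases with which the virus and whitefly index sequences both begin. It was listed in those 2 libraries alone, so an effect of the index cannot be told apart from a response to the virus.

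Among tags counted in all 4 libraries and chosen after their values were seen, CATGGCAAACTGCAGTGAGAA was 8.43-fold higher in virus than in mock (95% interval 7.22 to 9.94), at 420.6 against 49.8 TPM. CATGTGATCTTATTTATGATC was 9.65-fold higher (7.69 to 12.4), at 218 against 22.5 TPM. CATGTCATTTCTGATGGAACA was 10.9-fold lower in virus (8.55 to 14.2), at 19.3 against 212 TPM, and CATGTGCAAAATACCAACACA was 7.28-fold lower (5.67 to 9.58), at 19.04 against 139 TPM. These 4 tags had to be listed with centring to be chosen. Their centred folds were 7.04 to 17.6 in the same direction, the highest being that of CATGGCAAACTGCAGTGAGAA.

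The comparison of infested with mock plants sets the whitefly library against mock, without the virus in either. In the whitefly library 4396 tags were listed higher and 4889 lower, of 27662. Centring turned the balance, to 3987 higher and 3402 lower. Both largest rises were tags of unprinted sequence with 1913 and 1567 copies in whitefly, 760 and 66 in the joint library and none listed in mock or virus. Both largest falls were the 2 mock tags CATGCAAGAGTGCTAATTACT and CATGGGACACTACACATCTCG described above.

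Of tags counted in all 4 libraries, again chosen after their values were seen, CATGGCAAACTGCAGTGAGAA was 17.5-fold higher in whitefly than in mock (15.0 to 20.5), at 872 TPM, and 39.5-fold after centring. CATGGGTAATTGGAGCAGCCG was 9.22-fold higher (8.12 to 10.5), at 681 TPM in whitefly against 73.7 in mock, 20.2 in virus and 74.3 in the joint library. CATGGTACCTGAAATACTGGC was 12.8-fold lower (10.6 to 15.7), at 34.4 TPM in whitefly against 442.5 in mock. CATGCGAATACAATTAATGGC was 9.32-fold lower (7.71 to 11.5), at 33.8 TPM in whitefly, while mock, virus and joint held 316, 382 and 432 TPM.

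The joint treatment against mock listed 7356 tags higher and 6198 lower, of 29724. After centring 5678 were higher and 3995 lower. The 2 largest rises were CATGAAGATTTGCGTATTTAG, with 1858 copies, and CATGATCTAAAATTAGATCAG, with 1708, both listed in the joint library alone and ending in 4 and 9 bases of its index sequence. Both largest falls were the same 2 mock tags as before. Of tags counted everywhere and chosen after their values were seen, CATGGATGATGATGCCCCAGC was 7.48-fold higher (6.91 to 8.12), at 1474 TPM against 197. CATGGGAAACATTGTTCACCT was 14.0-fold lower in the joint library than in mock (10.9 to 18.4), at 19.01 against 267 TPM. CATGTCTGGTATCCAAAATGT stood at 208 TPM in mock, 52.4 in virus, 39.2 in whitefly and 17.8 in joint, 11.6-fold lower in the last than in the first (8.96 to 15.4).

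**Figure D1:**
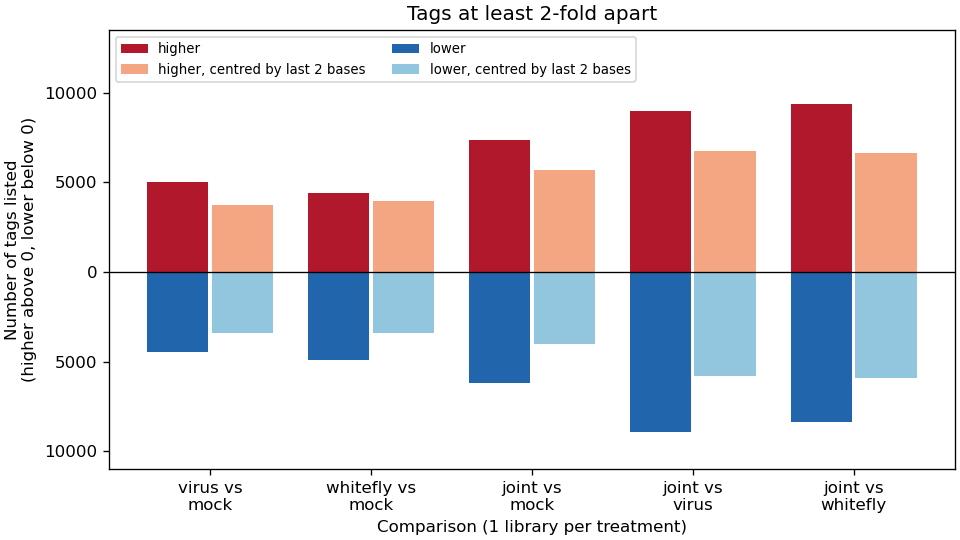
Numbers of tags listed as at least 2-fold higher (bars above 0) or lower (bars below 0) in each comparison of 2 libraries, before and after centring folds on tags with the same last 2 bases. Centring lowered every count, for example from 9384 to 6650 higher tags in the joint library against whitefly.

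Feeding on infected plants was read from the joint library against virus, where 8989 tags were listed higher and 8901 lower, of 31811, and after centring 6772 and 5799. By the naming rule the rises were again CATGAAGATTTGCGTATTTAG and CATGATCTAAAATTAGATCAG, and the falls CATGCAAGAGTGCTAATTTGA and CATGTTGAGCTTTAAGGATTG. Of tags counted everywhere and chosen after their values were seen, CATGTCGGACTGTAGAACTCT was 19.8-fold higher (18.0 to 22.0), at 2269 TPM against 114, and it stood at 1021 TPM in whitefly and 313 in mock. Tags were screened for index sequences and runs of A but not for adapter sequences, so this tag is not known to come from tobacco. An adapter source is not excluded for it, and its rise is not read as a response of the plants. CATGGAGACTGTCGATGCTCA was 18.0-fold higher (15.0 to 22.0), at 598 against 33.0 TPM. CATGGGAAACATTGTTCACCT was 31.1-fold lower (24.5 to 40.8), at 19.01 against 596 TPM, and CATGTGATCATTTGTGTATCT was 14.0-fold lower (10.6 to 19.1), at 15.2 against 214.5 TPM.

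Infection of infested plants was read from the joint library against whitefly, where 9384 tags were listed higher and 8346 lower, of 30996, and after centring 6650 and 5883. The rises by the naming rule were once more CATGAAGATTTGCGTATTTAG and CATGATCTAAAATTAGATCAG. The falls were CATGGTGATTATTCTGGACTA, with 1404 copies, and CATGCAAGAGTGCTAATTTGG, with 1162, both listed in whitefly alone and ending in 7 and 3 bases of its index sequence. Of tags counted everywhere and chosen after their values were seen, CATGGAGACTGTCGATGCTCA was 18.1-fold higher (15.0 to 22.2), at 598 against 32.9 TPM. CATGCGAATACAATTAATGGC was 12.7-fold higher (10.6 to 15.6). CATGGAAATAACAACAAACTC was 19.99-fold lower (15.5 to 26.6), at 17.3 against 348 TPM, or 10.7-fold after centring, and CATGGGTAATTGGAGCAGCCG was 9.15-fold lower (8.04 to 10.5). Scaling by DESeq2 size factors shifted folds of the joint library against virus by 0.12 on the log2 scale; no other comparison shifted by more than 0.09 under TMM or DESeq2 scaling.

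The 4 libraries give 2 estimates of each effect from separate libraries. Of 4285 tags listed in both estimates of the virus effect, 893 moved the same way with and without whiteflies, or 20.8% (exact interval 19.6 to 22.1), and the log2 folds had a correlation of −0.38 across 23561 tags. The share was 6.98% at a threshold of 4-fold and 9.51% with the interval wholly beyond 2-fold. After centring it was 27.0% and the correlation −0.22. Both estimates listed 581 tags higher, where independent lists would share 771, and 312 lower, where independent lists would share 1007. Of 4241 tags listed in both estimates of the whitefly effect, 1102 moved the same way with and without the virus, or 26.0% (24.7 to 27.3), 27.8% at 4-fold, 26.6% with the interval beyond 2-fold and 31.7% after centring. Their correlation across 23773 tags was −0.06 and turned to 0.14 after centring. Tags are not independent replicates, so no p-value goes with these values.

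Responses to the virus alone and to the whitefly alone, which share the mock library, had a correlation of 0.75 across 24784 tags. Unchanged libraries simulated with counting noise alone gave 0.56 from the shared mock library, and a covariance of 0.066 against 1.25 observed. Both lists held 1101 tags higher, against 279 for independent lists, and 2800 lower, against 882. Of the 3987 tags in both lists 97.8% moved the same way. The simulated unchanged libraries placed 55.1 tags in both lists on average, all of which moved the same way, so the shared library alone can give a share this high. There is 1 mock library, so it could not be split, and part of the excess may come from that library.

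The joint library departed from the sum of both single effects by at least 2-fold, beyond counting error, for 9105 tags above and 10200 below the sum, of 35700. After centring 7490 lay above and 6896 below. CATGTAATGTTTTGTTGTACA, for example, was 2.38-fold lower in virus than in mock and 2.77-fold higher in joint than in whitefly.

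The last 2 bases of a tag held a larger share of the fold variance than other adjacent pairs of bases in all 5 comparisons. They accounted for 18.4%, 13.2% and 21.8% of the variance of log2 folds of virus, whitefly and joint against mock, and for 32.7% and 34.6% of joint against virus and against whitefly. Among the other pairs up to base 19 no pair passed 2.08%. In the joint library against mock the median log2 fold was 1.962 over 564 tags ending in CC, 0.79 over 2282 ending in AA and −1.79 over 3122 ending in TT.

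**Figure D2:**
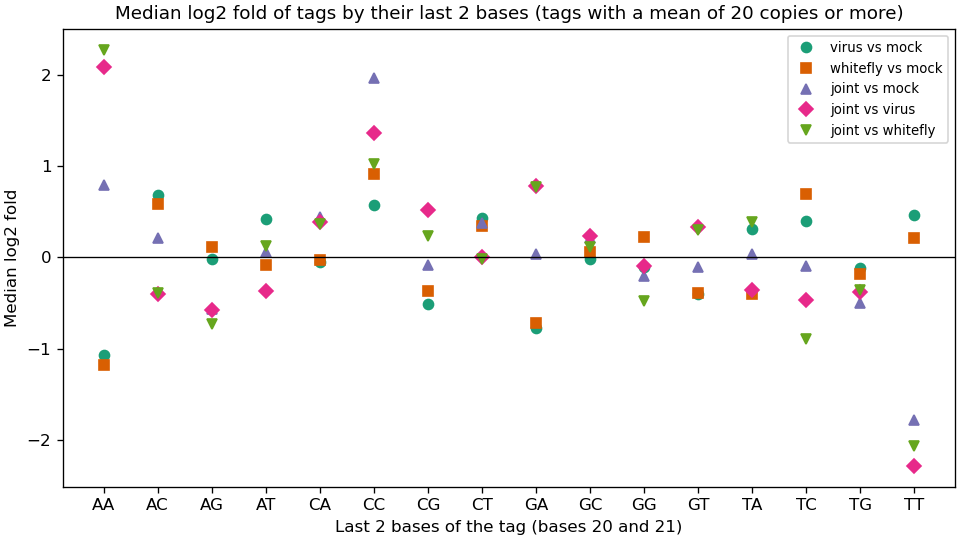
Median log2 fold of tags with a mean of at least 20 copies, by the last 2 bases of the tag (horizontal axis), with 1 symbol per comparison. Tags ending in TT lie at −1.79, −2.29 and −2.07 in the 3 comparisons of the joint library, and those ending in AA at 0.79, 2.08 and 2.27.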

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

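The tag CATGTAATGTTTTGTTGTACA was singled out because the virus effect on it went opposite ways in plants without and with whiteflies. Its log2 fold was −1.25 from mock to virus and 1.47 from whitefly to joint. After centring by the last 2 bases these were −1.20 and 1.10. Each value rests on 1 library per treatment, and the difference between them was set against counting error only.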

How the results depend on the processing

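The alternatives that centre by the last 2 bases, leave out tags with index bases, or give the additive fit an offset were chosen after seeing the data; the others were planned. No paired analysis was possible because each treatment has 1 library. The gene-list, nearest-site and multiple-match alternatives were not run, since no tag was assigned to a gene. Under edgeR TMM factors and DESeq2 size factors every count stayed within 1.5 times its designed value, and no same-direction share moved beyond its binomial interval. The correlations cannot move with these scalings, which shift all folds of a comparison alike. These scalings did turn the balance of virus against mock, where the higher tags made up 53.0% of those listed by design, 46.85% with TMM and 48.5% with DESeq2. Each tag named for its rise or fall kept its direction and stayed listed under these scalings, a prior of 5 and centring. For tags chosen after their values were seen, being listed with centring was a condition of choice, so it is no test. Tags named by the rule were missing from the lower library, with folds too large for centring to undo. The most abundant tags did not all do so. CATGTGGAAGCTACCTATGTT turned from a log2 fold of 0.036 in virus against mock to −0.053 with TMM, −0.026 with DESeq2 and −0.43 with centring, and in whitefly against mock to −0.095 with centring; its falls in joint against mock, virus and whitefly were no longer listed after centring, at −0.64, −0.18 and −0.48. CATGTTTGGGTGCACTGATGC turned with centring to −0.044 in joint against mock and −0.21 against virus, CATGTTCGGGTGCACTGATGC in joint against virus to 0.00025 with TMM and 0.11 with DESeq2, and CATGCAGCAAAGACCAAGAAC in whitefly against mock to −0.32 with centring; none of these was listed by design. The fall of CATGCAGCAAAGACCAAGAAC in joint against whitefly was no longer listed after centring, at −0.95, and CATGGACTCAAGGAGGTCAAG became listed in virus against mock with TMM, at −1.01, and in joint against mock with centring, at 1.05. The smallest fold the counts resolve depends on depth, since 1 copy is worth 0.280 to 0.297 TPM. The causes of the changes below were not tested, except that a stricter or looser threshold changes counts by construction.

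The additive edgeR fit with Benjamini-Hochberg adjustment called 0 tags higher and 0 lower for the virus and 0 and 0 for the whitefly, of 12809, with 114 and 58 for the virus and 123 and 61 for the whitefly at an unadjusted p under 0.05. With the last 2 bases as an offset it again called 0 in each, with 92 and 85, and 73 and 73, unadjusted. At the spread fitted to these counts the simulated fit found 41 of 100 tags changed 8-fold and 0 of 100 changed 2-fold. The 0 calls therefore leave changes of both sizes open. The simulated counts held no interaction, while the interaction is the only residual of the real fit.

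Counts are given as higher and lower for virus, whitefly and joint against mock, then joint against virus and against whitefly. With no minimum count they were 7652 and 7301, 8182 and 8139, 13506 and 9702, 16817 and 13530, and 17241 and 13616. With at least 100 copies they were 1054 and 1049, 855 and 1032, 1468 and 1581, 1968 and 2272, and 1975 and 2051. At 4-fold they were 898 and 1474, 1667 and 1841, 3215 and 2541, 5199 and 4306, and 5451 and 4116. With the interval wholly beyond 2-fold they were 1237 and 1824, 1854 and 2065, 3655 and 2972, 5654 and 4887, and 5709 and 4649. Centring changed by over 1.5 times the lower tags of joint against mock, to 3995, and against virus, to 5799, or 3847 and 5663 without index-bearing tags as well. Tags above the additive sum became 15910 with no minimum and 2386 with at least 100 copies; tags below it became 2934 with at least 100 copies, 6290 at 4-fold and 6769 with centring and no index-bearing tags.

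The correlation of both virus effects became −0.22 with centring, −0.22 also without index-bearing tags, and −0.21 with no minimum. That of both whitefly effects was −0.021 with at least 100 copies, −0.10 with no minimum and −0.19 with a prior of 5, and it reversed to 0.14 with centring, with or without index-bearing tags. The correlation of virus and whitefly responses became 0.73 with centring, 0.73 without index-bearing tags, 0.68 with both, 0.82 with at least 100 copies, 0.71 with no minimum and 0.70 with a prior of 5. The same-direction share of the virus effect became 27.0% with centring, 26.8% also without index-bearing tags, 6.98% at 4-fold, 9.51% with the interval beyond 2-fold and 18.1% with a prior of 5. For the whitefly effect it became 31.7%, and 31.9% without index-bearing tags, 27.8% at 4-fold and 27.6% with no minimum. For virus against whitefly, where the shared mock library gives a share near this without any change, it became 99.9% at 4-fold, 99.2% with the interval beyond 2-fold and 98.7% with a prior of 5.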

Other observations

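All tests in this part were chosen after the results were seen. As a hypothesis, some tags could be tied to proteins by translation. Amino acid sequences of 10 abundant or defence-related plant proteins were written from memory, and 58758 tags with at least 20 copies in total were searched for stretches of 6 identical residues. After tags 1 base away from a tag 50 times as abundant were left out, 67 tags matched. For 100 sets of shuffled sequences the median was 3 and the highest 8. Only some of the sequences, osmotin and chitinase among them, were written down before their tags had been seen. Shuffled sequences do not allow for this, so the excess does not settle how many matches arose by chance. A match names a candidate protein family and no gene, and tobacco carries several copies of each.

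The next hypothesis tested was that of PR-protein tags higher under whitefly feeding, PR standing for pathogenesis-related. Of 9 such tags with at least 20 copies in a library, 8 were listed higher in whitefly than in mock and none lower, and 6 were listed higher after centring. The largest was CATGACTCAAATACTTGTGCA, which encodes HDSNTCA as in PR-1, a salicylate-linked marker of defence, with 1157 copies in whitefly, 138 in joint and none listed in mock or virus. CATGAAACTACAGGAGGATGG, matching a basic chitinase, stood at 1346 TPM in mock, 811 in virus, 2697 in whitefly and 2314 in joint, and was 2.003-fold higher in whitefly than in mock, a fold that fell under 2 after centring. CATGCAATTCATTGTACGGCT, matching osmotin, stood at 6.83, 6.44, 22.5 and 46.2 TPM. The PR-1 sequence was written down after its tags had been seen, while osmotin and chitinase were written down before; of the 5 tags of the latter pair, 4 were listed higher in whitefly than in mock and 2 after centring, which leaves the hypothesis open. In the joint library against whitefly, 3 of the 4 PR-1 tags were listed lower and none higher, with and without centring. Of all 9 PR-protein tags, 4 were listed lower and 2 higher in that comparison, with and without centring.

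Of 16 tags matching photosynthesis proteins, 7 were listed lower in the joint library than in mock and none higher, or 8 lower and 2 higher after centring, which leaves a fall in photosynthesis transcripts as a possible explanation that these counts do not settle. The 2 higher ones, CATGTGGAAGTTGCCCATGTT and CATGTGGAAGCTGCCCATGTT of the Rubisco small subunit, had log2 folds of −0.32 and −0.52 without centring and 1.47 and 1.26 with it. Of the 9 tags matching the light-harvesting protein Lhcb1, 5 were lower, or 7 after centring, and none higher; among the 7, CATGCCCAGAGCATCCTCGCC turned from 0.64 to −1.32. CATGTTTGGATTCTTTGTTCA, which encodes MFGFFV of that protein, stood at 97.9 TPM in mock, 140 in virus, 66.5 in whitefly and 31.6 in joint. The 3 most abundant tags of the mock library, reported above, encode MFGCTD or MWKLPM of the Rubisco small subunit. In joint against mock the 2 MFGCTD tags had log2 folds of 0.54 and 0.17, or 0.33 and −0.044 after centring. The MWKLPM tag among them had −2.43, or −0.64 after centring. Of 10 histone tags, 5 were listed higher in virus than in mock, 4 after centring, and none lower. In joint against whitefly none of them was listed higher and 2 lower, or 4 higher and 1 lower after centring. CATGCCAAAGGACATTCAGCT, encoding MPKDIQ of histone H3, stood at 275 TPM in mock, 798 in virus, 440 in whitefly and 277 in joint. Among actin and ubiquitin tags, 1 of 10 was listed in virus against mock and 3 of 10 in whitefly against mock, or 1 and 1 after centring. A ubiquitin tag of unprinted sequence, not among the 10, had 9 copies in mock, 7 in virus, 401 in whitefly and 58 in joint, and was listed higher in whitefly than in mock with and without centring.

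The tags at least 2-fold apart between the joint and mock libraries invite a technical reading first. An effect of the tag's last 2 bases fits, with 21.8% of the fold variance against at most 0.778% for another pair of bases up to base 19, and a candidate source is ligation of a library-specific adapter to the tag end. A shift shared by all tags with the same last 2 bases is not the whole cause, since 8186 of the 13554 listed tags stayed listed in the same direction once it was removed, and 7274 did so once the shift shared by tags with the same last 4 bases was removed. Tags holding 6 index bases are not the whole cause either, because 13195 remained without them. Tags ending in fewer index bases were kept, so their part was not measured. An effect of the tag end that varies among tags with the same last bases is not excluded, as the quartiles of log2 folds lay up to 2.26 apart within an ending, in TC. A response of the plants stays open and cannot be told apart from such an effect or from further differences between single libraries: both centred estimates of the whitefly effect had a correlation of 0.137 across tags with 31.7% of tags listed in both moving the same way, and those of the virus effect −0.22 with 27.0%.

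Of tags with at least 20 copies in 1 library and none listed elsewhere, the share that held or ended in that library's own index sequence was 63.8% in mock, 98.1% in virus, 55.8% in whitefly and 30.3% in joint. By the same count 21.9% of such whitefly tags matched the mock index, whose first bases ACTAC also occur within the whitefly index. For every other pairing of a library with another's index the share was at most 3.03%. The start CATGGGAC was followed by the mock index in 1038 copies of mock, by the virus index in 635 copies of virus, by the whitefly index in 896 of whitefly and by the joint index in 950 of joint, and by none of them in another library.

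A set of 489 tags was nearly confined to the whitefly and joint libraries, with at least 10 copies in each and levels over 20 times those in mock and virus. They made up 2.25% of the whitefly and 1.25% of the joint copies. Whitefly RNA is a candidate source of the most abundant one, at 7340 TPM in whitefly, 5171 in joint, 3.98 in mock and 1.40 in virus, because it differed by 1 base from a general primer site in animal mitochondrial 16S rRNA; 6 of 58758 tags lay within 2 bases of that site and the next closest differed at 5. Of these 6, 3 belong to the set and the others have 16 to 19 copies in whitefly and 5 to 8 in joint, under the minimum of 10, with none listed in mock or virus. The most abundant tag had 24736 copies in whitefly. No filter for read errors was applied in this search, so the rarer tags near the site may be read errors of it. For the set as a whole whitefly RNA cannot be told apart from plant transcripts. The log2 ratio of joint to whitefly had an SD of 1.33 over the set, or 1.29 after centring by the last 2 bases. Over all tags with at least 20 copies in either library the SD was 2.31 without centring. Those tags could be absent from 1 of the 2 libraries, while the set needed at least 10 copies in each. The smaller SD of the set may follow from that minimum, so the 2 values are not comparable. Counting, the tag end and changes in the whiteflies can all spread the ratio of joint to whitefly, so its SD does not settle whether there was a single source. The 2 tags of the set that encode stretches of PR-1 do not settle it, since that sequence was written down after they had been seen.

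Tags shared by 2 libraries and not listed in the other pair, with at least 10 copies in each, numbered 482 for whitefly and joint, 16 for virus and joint, 107 for mock and joint, 29 for virus and whitefly, 4 for mock and whitefly and 3 for mock and virus. The most abundant virus and joint tag had 112 copies in virus and 739 in joint, a ratio of TPM values of 6.89 (exact 95% interval 5.64 to 8.49), and 4 others had ratios of 4.75 to 6.19. The tags with 54, 33 and 13 copies in virus and 27, 11 and 27 in joint had ratios of 0.522 (0.316 to 0.844), 0.348 (0.159 to 0.706) and 2.17 (1.08 to 4.58), and the intervals of the other 8 included 1. These ratios were not centred. In joint against virus the median fold was 4.23 upward for tags ending in AA and 4.87 downward for TT. Of the 16 tags, 5 ended in A. The ratios therefore cannot be told apart from an effect of the tag end. All 107 of the mock and joint tags ended in A, and 90 ended in AA. Of the 29 virus and whitefly tags, 19 ended in TG, with which the virus and whitefly index sequences both begin.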
